A study of Mus musculus with 12 samples.

How the data were processed

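Whole hearts of 52-week-old C57BL/6N mice were profiled by sequencing of total RNA, with ribosomal RNA depleted and cDNA primed by random hexamers, per the labels' protocols. The 6 total-RNA libraries fall into 2 groups by their labels. The 3 control libraries carry a Rexo2 gene flanked by loxP sites on both alleles, and the 3 knockout libraries carry the same alleles plus an allele named Ckmm, the name of the muscle creatine kinase gene whose promoter is commonly used to drive Cre recombinase in heart and skeletal muscle. Genotype thus covers both the Ckmm allele itself and any loss of Rexo2, which this design cannot tell apart. The table columns name a group and a library number but no replicate number, so a library is called here by its group and that number, such as control 490. Nothing in the labels ties each library to its own animal, so the p-values measure the spread between these samples, which may be partly technical. The series also holds libraries of RNA ends from heart mitochondria, 3 per group, which are not analysed here.

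The expression values are signal per gene that the authors deposited as normalised counts, made with Bowtie2 2.3.4.1, bedtools, featureCounts, R 3.5.2 and DESeq2 1.22.2, per the submitters' processing notes, which name the genome builds mm10 and GRCm38 without their roles. Whether reads were counted by strand is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may not be separated. The authors also deposited a DESeq2 table of the comparison, whose log2 fold changes, test score and p-value columns, with adjusted values, are used only as the authors gave them. A feature without an adjusted p in that deposited table was kept as missing. The count table lists 54751 features, of which 54715 have Ensembl identifiers and 36 are encoded by mitochondrial DNA (mtDNA). Ensembl features were joined to symbols for 54686 of the 54715. Among the mtDNA features, the authors merged mt-Atp8 with mt-Atp6 and mt-Nd4l with mt-Nd4, whose reading frames overlap. Gene positions are from a RefSeq annotation of GRCm38, 1-based.

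Dividing each library's values by the worth of 1 read gave whole numbers for 100% of the 156689 nonzero values, within a tolerance of 0.01. The recovered totals were 50764023, 48006165 and 43561069 reads in control 490, 498 and 502, and 43867377, 49722049 and 41979163 in knockout 492, 499 and 501. No pair of libraries in a group agreed within counting noise, with a chi-square per degree of freedom from 3.52 to 15.0, so all 6 were counted as separate samples.

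The deposited values were tested on the scale log2(value + 1), which understates the change of low genes, for the 18250 features with a mean of at least 10 over the 6 libraries. The test was limma 3.58.1 with a trended prior, 2-sided, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Tests were run in R 4.3.3. On simulated counts for 18250 genes with the real means and depths, the fit recovered 12% of 50 genes changed by 1.2-fold, 76% of those changed by 1.5-fold and 100% at 2-fold and 3-fold, and called 7 of 18020 unchanged genes. The changed genes were drawn from those with a mean of at least 50. Genes were simulated independently of each other, so recovery in the real libraries may be lower. The many changed genes of the simulation, among them 50 at 2-fold and 50 at 3-fold, also loosen its Benjamini-Hochberg cutoff. The real fit called 4 features, so its cutoff was stricter and its recovery likely lower. The median standard error of a log2 fold change was 0.12, and a typical gene needed a log2 fold change of 0.27 to reach an unadjusted p of 0.05.

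Gene lists for pathways, complexes and cell types were fixed before the data were examined, 36 in all, as were the designs and the rule for naming genes. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The other 7 had too few members and are described by their medians. The named genes are Rexo2, all mtDNA mRNAs and rRNAs, up to 12 genes per direction with the largest log2 fold change among those past the threshold with a mean of at least 50 and no overlap between groups, and for each list up to 4 called members or, where none was called, the 2 members of smallest p. Predicted and unnamed genes were left out by that rule, and any feature named outside it is said to be so. A member that the rule names in the sarcomere and calcium handling list is not reported here. Per-library ratios and shares were compared by exact permutation tests, 2-sided, which with 3 libraries against 3 cannot give a p below 0.1.

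Alternatives covered the pseudocount, the filter, 3 other scalings, limma without a trend or with robust moderation, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the authors' deposited table, camera with an estimated correlation, limma's fry, and leaving out each library in turn. Camera with an estimated correlation had little power with 3 libraries per group, and its smallest adjusted p was 0.83. For the biogenesis regulators the estimated correlation was -0.0233, below the preset 0.01, yet camera's unadjusted p rose from 0.0617 to 0.118. The preset in turn lies below the 0.367 estimated for the interferon-stimulated genes, so neither setting settles a list call. On the recovered reads edgeR called 5 features and DESeq2 called 33. After seeing the data, a restriction to features with an adjusted p in the authors' table, a covariate for the fatty acid oxidation score, refits of camera with an estimated correlation, and a share of the reads not on mt-Rnr2 were added.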

Results

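Total RNA of hearts from 52-week-old mice was compared between 3 libraries labelled control and 3 labelled knockout for Rexo2, which encodes an oligoribonuclease that degrades short RNA fragments, including dinucleotides, in mitochondria and the cytosol. The series title names dinucleotide regulation and promoter specificity in mitochondria, so the comparison bears on mtDNA-encoded transcripts as well as nuclear ones. Depth ranged from 41979163 to 50764023 reads per library. The Y-linked gene Ddx3y lay between 1268 and 1623 normalised counts and Xist between 0.94 and 2.68 in all 6 libraries. On the first principal component, with 26.4% of the variance, control 490 stood apart at -30.1 while the other libraries lay between -5.63 and 16.7. The third component, with 18.2%, held the controls at -13.7, -12.9 and -11.3 and the knockout-labelled libraries at 3.91 to 18.0.

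Rexo2 (ENSMUSG00000032026.7, chromosome 9, 48468512 to 48480611) was measured at 330 ± 37.3 normalised counts (SD, n = 3) in control and 292 ± 20.2 in knockout-labelled hearts. The libraries held 330, 368 and 293 counts in control 490, 498 and 502, and 274, 288 and 314 in knockout 492, 499 and 501, so the groups overlapped. Its log2 fold change was -0.17 with an SE of 0.10, a 95% interval from -0.39 to 0.04 and a limma adjusted p of 1.00. Counts are per gene and the labels used here do not give the deleted exons, so the count does not check the labels, and knockout refers to the label throughout.

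The clearest change among nuclear genes was a lower level of Ghitm, which encodes a protein of the inner mitochondrial membrane. Ghitm (ENSMUSG00000041028.16, chromosome 14, 37120444 to 37135322) fell from 4746 ± 47.9 to 2996 ± 178 normalised counts (SD, n = 3 per group), a log2 fold change of -0.67 with an SE of 0.051 and a limma adjusted p of 9.58e-05. Cpe (ENSMUSG00000037852.8, chromosome 8, 64592542 to 64693109), which encodes carboxypeptidase E, a processing enzyme of peptide hormones, fell from 1397 ± 24.0 to 977 ± 41.3, with a log2 fold change of -0.52, an SE of 0.057 and a limma adjusted p of 0.00399. Pdha1 (ENSMUSG00000031299.10, chromosome X, 160122219 to 160138430), the E1 alpha subunit of pyruvate dehydrogenase, fell from 13224 ± 39.2 to 10538 ± 263, with a log2 fold change of -0.33, an SE of 0.042 and a limma adjusted p of 0.0126. The fourth call was the transcribed pseudogene 4930519F09Rik (ENSMUSG00000090126.1, chromosome 10, 28921635 to 28923567), outside the naming rule and named after its values were seen, which fell from 1722 ± 11.4 to 1335 ± 12.1, a log2 fold change of -0.37 with a limma adjusted p of 0.0250.

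**Figure D1:**
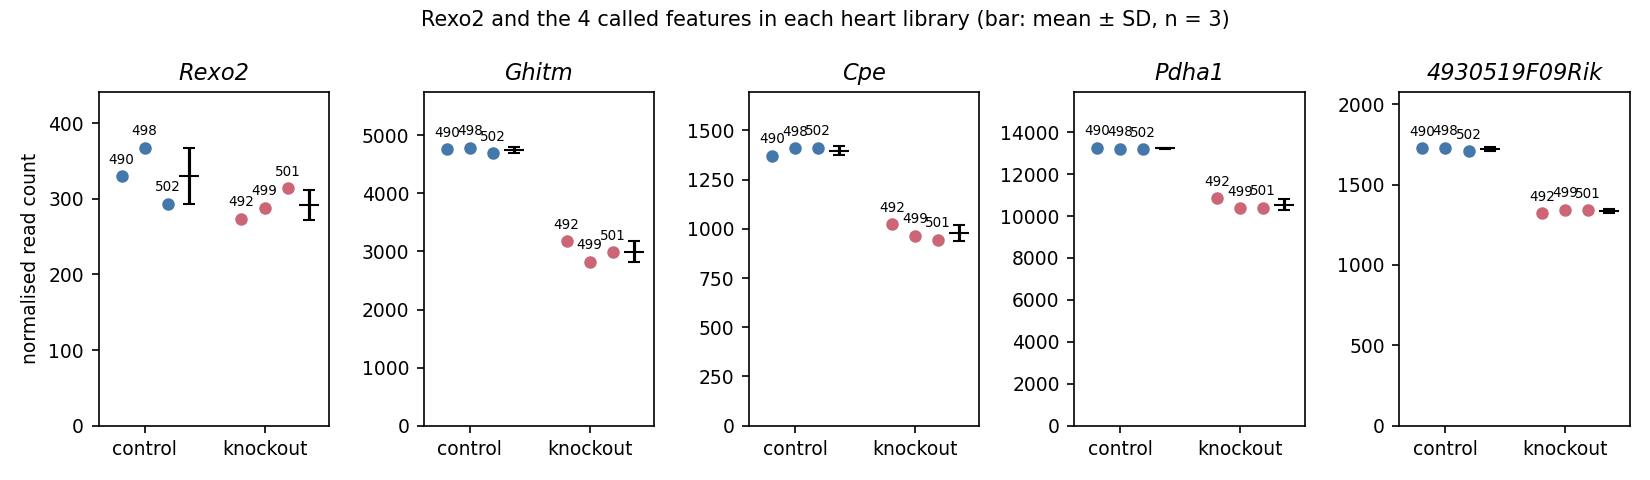
Normalised read counts of Rexo2 and the 4 called features in each heart library, with 1 point per library marked by its number and a bar for the mean ± SD of 3 libraries. Rexo2 overlaps between the groups, whereas Ghitm, Cpe, Pdha1 and 4930519F09Rik lie lower in all 3 knockout-labelled libraries than in all 3 controls.

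Of the 18250 features tested by limma, these 4 were called, all lower, and 0 were called higher. At an unadjusted p under 0.05 limma had 675 features, 313 higher and 362 lower, a smaller share than the 0.05 that no effect would give. At an adjusted p under 0.05, edgeR called 2 features higher and DESeq2 called 4. Groups did not overlap in 1735 features, 9.51% of those tested, where chance gives 10% for 3 against 3. Ghitm was called in each of the 6 fits that left out 1 library. Cpe lost its call without control 498 (limma adjusted p = 0.102), knockout 499 (0.0617) or control 502 (0.0655), and Pdha1 without control 498 (0.241), knockout 499 (0.174), knockout 501 (0.0536) or control 502 (0.0694) and under edgeR (0.0598). The call of 4930519F09Rik was lost without knockout 492 (limma adjusted p = 0.113), control 498 (0.256), knockout 499 (0.174), knockout 501 (0.0682) or control 502 (0.102). Without a trended prior limma called 0 features, with Ghitm at an adjusted p of 0.589.

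The deposited table of the authors called 33 features at an adjusted p under 0.05, 29 lower and 4 higher, and these included all 4 limma calls. All 33 had the same sign in limma and no overlap between the groups, and DESeq2 on the recovered reads called 33, all 33 shared. The authors' deposited table gave adjusted p-values to 7550 features, the lowest with a mean of 246.8 counts. Besides Ghitm, Cpe and Pdha1, the lower calls in the authors' deposited table included Suclg2 (log2 fold change -0.37) and Sucla2 (-0.23), subunits of succinyl-CoA synthetase, Atp5a1 (-0.23), the alpha subunit of ATP synthase, Echs1 (-0.33) and Hadhb (-0.34), enzymes of fatty acid oxidation, and Pink1 (-0.31), a mitochondrial kinase. The 4 higher calls of the authors' deposited table were H2-K1 (0.37) and H2-Q6 (0.57), which encode MHC class I chains, and Gbp4 (0.63) and F830016B08Rik (0.51). These genes beyond the limma calls were named from the deposited table after its values were seen. Of the 33, 5 were annotated as pseudogenes. Gm13910, a pseudogene of Hadhb, held 28430 ± 2560 counts in control against 6523 ± 645 on Hadhb itself, and how reads of these near-identical sequences were divided is not given in the sources used here, so both are uncertain, as are H2-Q6 and H2-Q7. Other MHC class I genes may share reads as well.

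Over the 658 tested members of the fixed lists, limma called 1, Pdha1, with 36 at an unadjusted p under 0.05, 20 higher and 16 lower. edgeR called 1 member, mt-Rnr2. DESeq2, which gave an adjusted p to 473 of the members, called 6, all lower, Pdha1, Suclg2, Sucla2, Atp5a1, Echs1 and Hadhb. The tricarboxylic acid (TCA) cycle list had 1 called member of 19, Pdha1. Adjusted over the list alone, 3 members were lower, Pdha1, Suclg2 (limma log2 fold change -0.37, list-alone adjusted p = 0.000514) and Sucla2 (-0.23, 0.00133), while 0 were higher. The list as a whole did not pass limma's camera test, with 8 of 19 members above 0, a median log2 fold change of -0.0039 and an adjusted p of 0.0705, and its adjusted p was 0.830 with an estimated correlation. limma's fry test gave an adjusted p of 0.948 for change in 1 direction and of 0.00143 for change in either direction. Among the 33 calls of the authors' deposited table, 3 were on this list where 0.083 were expected from the 7550 features with an adjusted p, and Fisher's exact test, 1-sided, gave p = 7.03e-05, or 0.00141 adjusted over 20 lists. Fisher's test treats genes as independent, whereas the estimated correlation within this list was 0.204. Its p therefore does not measure the spread between libraries. Leaving out 1 library gave camera adjusted p-values of 0.341 without control 490, 0.390 without knockout 499, 0.107 without knockout 501, 0.0851 without control 498, 0.00581 without control 502 and 0.00420 without knockout 492. Scaling to equal totals, which shifts all features alike and the median log2 fold change by -0.069, brought it to 1.23e-05. With an estimated correlation, 0 of the 29 lists passed under equal totals or without any 1 library, and the adjusted p of this list was at least 0.685. Camera had little power in that setting, so these misses do not show that a list was unchanged.

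Fatty acid oxidation had 0 called members of 31. Adjusted over the list alone, Echs1 (log2 fold change -0.33) and Hadhb (-0.34) were lower, Hadhb not without control 498 (list-alone adjusted p = 0.0675) or knockout 499 (0.0730). The median was 0.019 with 20 members above 0 and the mean 0.0053, while the camera direction was down (adjusted p = 0.805). A single library decided both the call and the direction, which was up without control 490 (1.68e-05) or knockout 499 (0.0421) and down without control 502 (0.000735). With an estimated correlation the adjusted p was 0.939 with all libraries and 0.878, 0.918 and 0.899 in those 3 fits. The overlap with the authors' deposited calls was 2 of 29 members, with an adjusted Fisher exact p of 0.0699, which also treats genes as independent. Nuclear complex I subunits had 0 called of 36 (median 0.018, camera adjusted p = 0.514), with Ndufs8 at 0.071 and Ndufs3 at 0.074. That list was up at 0.0421 without knockout 499 (adjusted p = 0.775 with an estimated correlation), and its direction turned down without knockout 492 (0.609) or control 502 (0.840) and under equal totals (0.391). Complex II to V subunits had 0 called of 41, with Atp5a1 (-0.23) the 1 member lower when adjusted over the list alone, though not without control 498 (0.0615) or knockout 499 (0.0916), and Sdha at -0.11. Without a trended prior, limma's adjusted p over the list alone was 0.596 for Atp5a1, 0.236 for Echs1, 0.358 for Hadhb and 0.0711 for Sucla2, while Pdha1 and Suclg2 passed in all 20 alternatives. The median of the complex II to V list was 0.00035, whereas its mean was -0.0060 and its camera direction down (adjusted p = 0.822). The direction turned up without control 490 (0.334), knockout 499 (0.287) or knockout 501 (0.573), and the list was down at 0.0136 under equal totals and at 0.0042 without knockout 492, with adjusted p = 0.995 and 0.780 with an estimated correlation. Glycolysis had 0 called of 23 (median 0.027, camera adjusted p = 0.5), with Pkm at -0.12 and Pfkfb3 at 0.18, and its upward direction turned down under equal totals (0.860).

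For mtDNA-encoded transcripts, the mRNAs of both strands differed between the groups by less than the test could call. None of the 10 heavy-strand mRNA features was called by limma, where 1 was at an unadjusted p under 0.05. Their log2 fold changes ran from -0.048 for mt-Nd3 to 0.13 for mt-Nd5, with mt-Nd4l_4 at 0.12, mt-Cytb at 0.086, mt-Nd2 at 0.073, mt-Atp8_6 at 0.0058, mt-Nd1 at -0.012, mt-Co1 at -0.021, mt-Co3 at -0.034 and mt-Co2 at -0.041. The groups did not overlap in mt-Nd2, mt-Nd4l_4, mt-Nd5 and mt-Cytb, and overlapped in the other heavy-strand mRNAs. Within libraries, mt-Nd4l_4, mt-Nd5 and mt-Cytb minus the other heavy-strand mRNAs was higher by 0.124, with overlap (exact permutation p = 0.2). Scaling to equal totals, which shifts all features alike, moved mt-Atp8_6 to -0.064, and it was -0.021 without knockout 492. The sign also turned for mt-Nd1 without control 490 (0.014) or knockout 501 (0.045) and for mt-Co1 without control 490 (0.015) or knockout 499 (0.0053). The heavy-strand mRNAs as a list had a median of -0.0029, a mean of 0.026 and an upward camera direction (adjusted p = 0.470) that turned down under equal totals (0.956).

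The light-strand mRNA mt-Nd6 held 9996 ± 2283 counts in control and 9069 ± 392 in knockout-labelled hearts (SD, n = 3), a log2 fold change of -0.12 with a 95% interval from -0.36 to 0.13. Single libraries decided its direction, with 0.042 without control 502 and -0.295 without control 490. The list of mt-Nd6 and the light-strand tRNAs had 0 called of 9 (median -0.041, camera adjusted p = 0.822), with mt-Tq at -0.11, and its direction turned up without control 498 (0.654), knockout 501 (0.654) or control 502 (0.908) and under equal totals (0.956). Within each library, the mean log2 value of this list minus that of the heavy-strand mRNAs was -12.6 ± 0.17 in control and -12.6 ± 0.065 in knockout-labelled hearts, a difference of -0.056 (exact permutation test, 2-sided, p = 0.7). The difference was 0.022 without control 498. For mt-Nd6 alone against the heavy-strand mRNAs it was -0.14 (exact permutation p = 0.6). Heavy-strand tRNAs had 0 called of 12 tested (median 0.094, camera adjusted p = 0.298), with mt-Tl1 at 0.19 and mt-Tt at 0.51, and the direction turned down without knockout 492 (0.993). Mature tRNAs are short and poorly captured by such libraries.

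**Figure D2:**
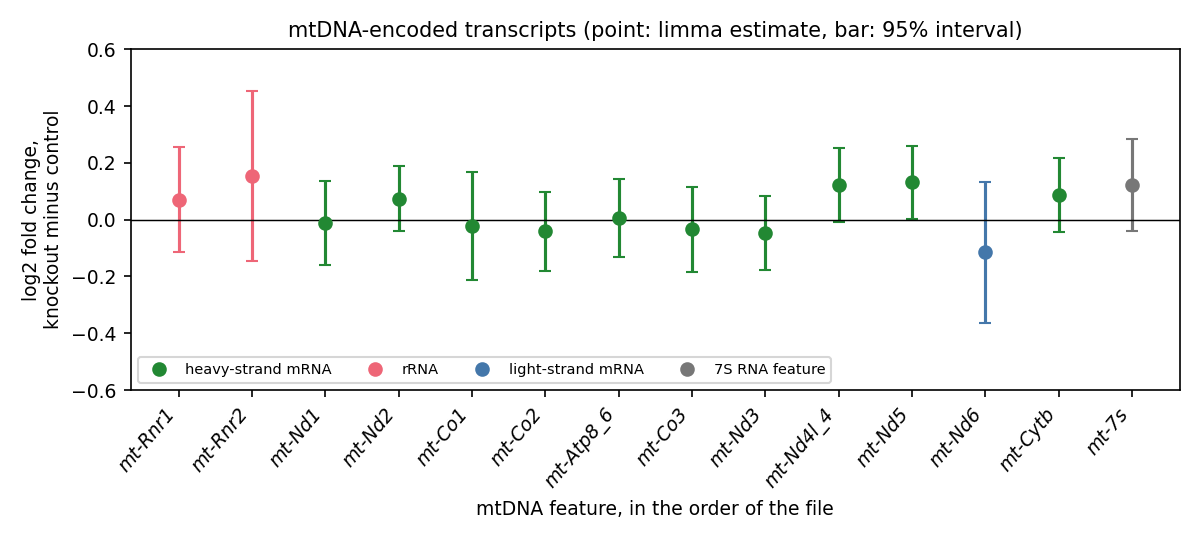
Log2 fold change, knockout minus control, of each mtDNA mRNA, rRNA and 7S RNA feature as fitted by limma from 3 libraries per group, in the order of the mtDNA features, with bars for the 95% interval. Estimates lie between -0.12 for mt-Nd6 and 0.15 for mt-Rnr2, and the interval leaves out 0 for mt-Nd5 alone, whose adjusted p was 1.00. The wide interval of mt-Rnr2 reflects the trended prior, and its groups do not overlap. Under equal totals, which shift all features alike, mt-Atp8_6 changes sign.

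The 16S rRNA mt-Rnr2 (mtDNA, 1094 to 2675) was the most abundant feature. It held 20656000 ± 224100 normalised counts in control and 22996000 ± 276600 in knockout-labelled hearts (SD, n = 3) without overlap, a log2 fold change of 0.15. limma did not call it (adjusted p = 1.00), with an SE of 0.14. That SE reflects the trended prior more than the spread between these libraries, which was small as the SDs show. It was called by limma with robust moderation (adjusted p = 0.0321) and by edgeR (0.00143), not by DESeq2 on the recovered reads (0.0976), nor in the authors' deposited table (0.0978). The 12S rRNA mt-Rnr1 (70 to 1024) had a log2 fold change of 0.071, and mt-7s one of 0.12. The 7S RNA feature mt-7s is on no fixed list. Against the heavy-strand mRNAs it was higher by 0.0966 with overlap (exact permutation p = 0.4), where the light-strand list differed by -0.0559. The 2 rRNAs had a median of 0.11.

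Reads on all mtDNA features made up 69.6 ± 0.34% of the total in control and 71.6 ± 0.23% in knockout-labelled libraries (SD, n = 3), higher by 1.99 points with no overlap, and the exact permutation p of 0.1 is the smallest that 3 against 3 allow. Adjusted over 12 such measures it was 0.3. The share on mt-Rnr2 was 46.0 ± 0.42% and 48.8 ± 0.54%, higher by 2.78 points (exact permutation p = 0.1). Without the rRNAs the mtDNA share was 17.7 ± 0.21% in control and 16.9 ± 0.52% in knockout-labelled libraries, a difference of -0.794 points (exact permutation p = 0.1). Shares of 1 total are not independent, and of the reads not on mt-Rnr2, a measure added after the data were seen, 32.8 ± 0.14% and 33.0 ± 0.68% lay on mtDNA features other than rRNAs, a difference of 0.226 points (exact permutation p = 0.9). The share on mt-Rnr1 was 5.94% in both groups.

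**Figure D3:**
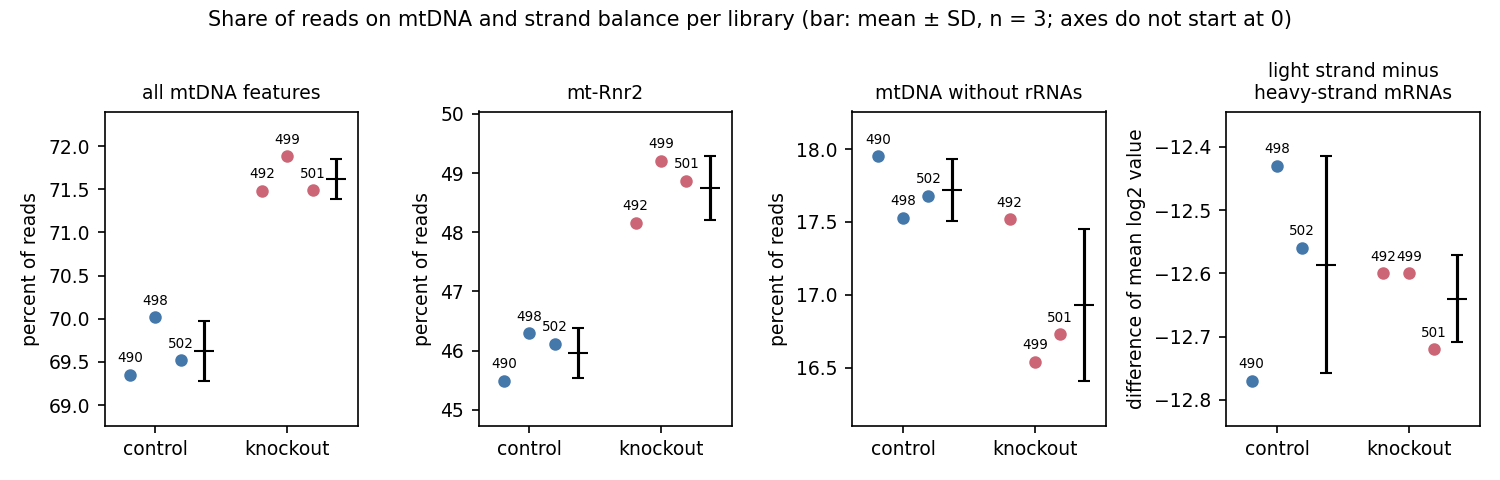
Percent of reads on all mtDNA features, on mt-Rnr2 and on mtDNA features other than rRNAs, and the light-strand minus heavy-strand log2 difference, with 1 point per library and bars for the mean ± SD of 3 libraries; axes do not start at 0. The share on mt-Rnr2 lies between 45.5 and 46.3% in controls and between 48.2 and 49.2% in knockout-labelled libraries, while the strand difference overlaps.

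Nuclear genes that act on mtDNA or its transcripts showed no call. Mitochondrial ribosomal proteins had 0 called of 79 (median 0.021, camera adjusted p = 0.514), with Mrpl57 at 0.20 and Mrps12 at 0.21. Factors of mtDNA maintenance and transcription had 0 called of 25, with a median of -0.0061, a mean of 0.012 and an upward camera direction (adjusted p = 0.743), and Tfb1m was at 0.27 and Mterf2 at 0.15. Mitochondrial RNA processing and decay had 0 called of 32 (median 0.0091, adjusted p = 0.514), with Mrm1 at -0.21 and Trnt1 at 0.16. Mitochondrial chaperones and proteases had 0 called of 17 (median 0.033, adjusted p = 0.298), with Clpp at 0.22 and Spg7 at -0.16, and was up at 0.0421 without knockout 499 (adjusted p = 0.775 with an estimated correlation). The mitochondrial integrated stress response had 0 called of 27 (median 0.032, adjusted p = 0.886), with Aldh1l2, a mitochondrial folate enzyme, at -0.48 and Atf5 at -0.16. Regulators of mitochondrial biogenesis had 0 called of 14 (median -0.036, adjusted p = 0.298), with Pprc1 at -0.24 and Ppard at -0.19, and was down at 0.0449 under equal totals (adjusted p = 0.685 with an estimated correlation).

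Interferon-stimulated genes rose as a list at the preset correlation. Of 37 tested members 33 lay above 0, with a median log2 fold change of 0.16 and a camera adjusted p of 7.44e-09, but the adjusted p was 0.830 with an estimated correlation and 0.948 in limma's fry test. limma called 0 members, with 9 higher at an unadjusted p under 0.05, and adjusted over the list alone 1 was higher, Tap1, the peptide transporter of MHC class I loading, which had a log2 fold change of 0.48 (168 ± 11.6 against 234 ± 20.7 counts, SD, n = 3). Over the list alone Tap1 missed the threshold under 6 of 19 alternatives, which were leaving out control 490 (adjusted p = 0.0776), knockout 492 (0.145), control 498 (0.116) or knockout 499 (0.148), equal totals (0.0960) and limma without a trended prior (0.0832). Rsad2, an antiviral enzyme, was at 0.42. The mean log2 value of the list, centred over the libraries, was -0.27, -0.12 and 0.13 in control 490, 498 and 502 and 0.18, 0.15 and -0.064 in knockout 492, 499 and 501, so the groups overlapped (exact permutation p = 0.2). Macrophage markers had 0 called of 15 (median 0.039, camera adjusted p = 0.470), with Adgre1 at 0.35 and C1qc at 0.13.

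Immediate early genes, which respond within minutes to stimuli such as handling of tissue, fell as a list at the preset correlation. Of 19 tested members 4 lay above 0, with a median of -0.11 and a camera adjusted p of 0.0348, and the adjusted p was 0.830 with an estimated correlation. None was called by limma, where 1 was lower at an unadjusted p under 0.05, with Klf4 at -0.31 and Fosl2 at -0.14. The list lost its call without knockout 492 (camera adjusted p = 0.603), control 498 (0.148) or control 502 (0.119), under equal totals (0.116), with no filter (0.0673), with a mean of at least 50 (0.0614) and in limma's fry test (0.948).

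**Figure D4:**
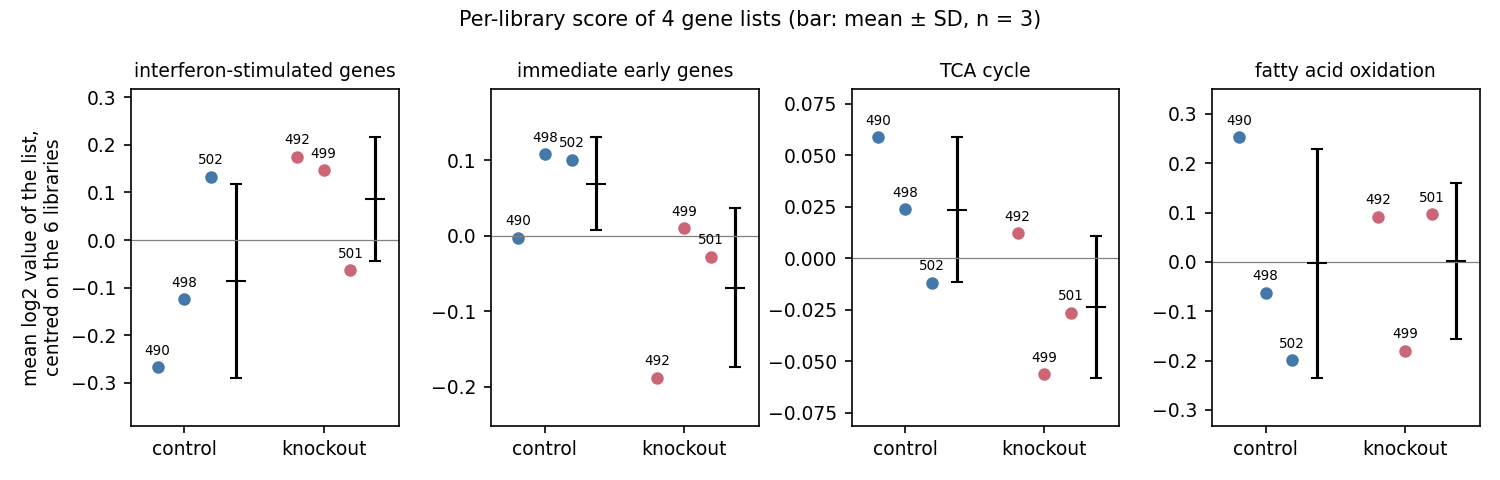
Mean log2 value of 4 gene lists in each library, centred over the 6 libraries, with 1 point per library and bars for the mean ± SD of 3 libraries. Interferon-stimulated genes lie between -0.27 and 0.13 in controls and between -0.064 and 0.18 in knockout-labelled libraries, and fatty acid oxidation spans -0.20 to 0.25 within the controls.

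Structural and stress genes of the heart showed no call. The cardiac stress and fetal programme had 0 called of 19 (median 0.015, camera adjusted p = 0.822), and adjusted over the list alone 1 member was higher, Acta1, skeletal alpha actin, at 0.64 (3361 ± 1045 against 5060 ± 663 counts, SD, n = 3; limma list-alone adjusted p = 0.0494), with Ccn1 at 0.25. Acta1 was at 0.35 without control 490, which held 2186 counts where the other controls held 3715 and 4183. Over the list alone it missed the threshold under 11 of 20 alternatives, among them leaving out control 498 (adjusted p = 0.0664), knockout 499 (0.163) or knockout 501 (0.135), with values from 0.000702 to 0.639. The list was up at 0.0334 without knockout 492 (adjusted p = 0.735 with an estimated correlation), and its direction turned down without control 490 (0.5), knockout 499 (0.549) or knockout 501 (0.679), under equal totals (0.993) and in limma's fry test (0.948). Sarcomere and calcium handling genes had 0 called of 30 (median -0.027, adjusted p = 0.336), with Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -0.16, and the list was down at 6.49e-05 under equal totals and at 0.0204 without knockout 492. With an estimated correlation its adjusted p was 0.830 with all libraries and 0.711 and 0.735 in those fits, and 0.948 in limma's fry test. Extracellular matrix genes had 0 called of 36 (median -0.00055, adjusted p = 0.805), with Cilp at 0.45 and Col3a1 at -0.12. That list was down at 0.0267 without knockout 499 (adjusted p = 0.775 with an estimated correlation), and its direction turned up without knockout 492 (0.0529) or control 502 (0.491). NRF2 targets had 0 called of 23 (median 0.020, adjusted p = 0.514), with Sod2 at -0.18 and Nqo1 at 0.18. Targets of p53 had 0 called of 15 (median 0.031, adjusted p = 0.743), with Trp53inp1 at 0.20 and Ccng1 at -0.095. Clock genes had 0 called of 18, with a median of -0.00066, a mean of 0.0076 and an upward camera direction (adjusted p = 0.886) that turned down under equal totals (0.952) and without control 498 (0.758) or knockout 501 (0.305), Bhlhe40 at -0.14 and Arntl at 0.33.

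With all 6 libraries, no marker list of another cell type passed the same test. Endothelial markers had 0 called of 14 (median -0.024, camera adjusted p = 0.759), with Eng at 0.071 and Vwf at -0.12. Fibroblast markers had 0 of 12 (median 0.030, adjusted p = 0.514), with Mmp2 at 0.14 and Dpep1 at 0.12. Smooth muscle and pericyte markers had 0 of 12 (median -0.034, adjusted p = 0.822), with Acta2 at 0.18 and Abcc9 at -0.090. Erythroid markers had 0 of 7 (median -0.030, adjusted p = 0.805), with Alas2 at -0.10 and Hbb-bs at 0.044, which turns negative under equal totals at -0.027 and without knockout 501 (-0.064) or control 502 (-0.066). The erythroid list was down at 0.0164 without knockout 501 (adjusted p = 0.822 with an estimated correlation), and its direction turned up without knockout 492 (0.144) or control 498 (0.430). Atrial myocyte markers had 0 of 7, with a median of -0.014 against a mean of 0.043 and a downward camera direction (adjusted p = 0.822) that turned up without knockout 492 (0.907), Nppa at -0.20 and Myl4 at 0.46. Schwann cell and neuronal markers had 0 of 7 (median -0.082, adjusted p = 0.405), with Dbh at -0.63 and Gfra3 at -0.54. Lists with too few tested members for camera were lymphocyte markers with 3 (median 0.22, Igkc at 0.33 and Ighm at 0.22), adipocyte markers with 2 (0.13, Lipe at 0.14 and Cidea at 0.11), skeletal muscle markers with 2 (0.20, Myl1 at 0.28 and Mybpc2 at 0.12), neutrophil and mast cell markers with 1 (Csf3r at 0.55), mesothelial markers with 1 (Wt1 at 0.12) and sex-linked genes with 4 (0.052, Kdm5d at 0.13 and Uty at 0.077). Leaving out 1 library turned Lipe (-0.085 without control 502), Cidea (-0.022 without knockout 492), Mybpc2 (-0.058 without knockout 499) and Wt1 (-0.115 without control 490) negative.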

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

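The restriction to features with an adjusted p in the authors' table, the fatty acid oxidation covariate, the estimated correlation in refits and the share of reads not on mt-Rnr2 were chosen only after the result was seen. No paired analysis was possible because the columns carry no replicate numbers. The count of 4 called features, 0 higher and 4 lower, was also 4 with pseudocounts of 0.5 and 8, a mean of at least 50, TMM scaling, scaling on nuclear genes and the added restriction, with all 4 shared. It moved to 12, 1 and 11 without a filter, to 37, 1 and 36 under equal totals, which shift the median log2 fold change by -0.069, to 12, 2 and 10 with robust moderation, and to 33, 4 and 29 with DESeq2 and in the authors' deposited table. edgeR called 5, 2 higher and 3 lower, limma without a trend called 0, and the added covariate gave 22, 4 and 18. The cause of these moves was not tested. Leaving out 1 library gave 1 to 8 calls, 0 to 1 higher and 1 to 7 lower, with 8 without control 490 and 1 without control 498, knockout 499 or control 502. The Rexo2 log2 fold change stayed between -0.26 and -0.094 when 1 library was left out and was never called. Lists past the threshold numbered 2, and 0 with an estimated correlation, also under equal totals or without any 1 library, 0 in fry's test of 1 direction and 1, the TCA cycle, in its test of either direction, 1 without a filter or with a mean of at least 50, 5 under equal totals and 1 to 6 when 1 library was left out. The mtDNA share without rRNAs differed by -0.794 points of all reads and by 0.226 of the reads not on mt-Rnr2, and leaving out 1 library kept the full share difference between 1.85 and 2.18. The strand difference ran from -0.149 to 0.0224 when 1 library was left out, positive without control 498. Of 1554 values of 81 named genes under the alternatives, 1508 kept their direction and side of the threshold, 17 lost the threshold, 15 gained it and 14 changed sign. The changes of sign were under equal totals, where a shift of all features alike turns values near 0, for mt-Atp8_6 (-0.0643) and Hbb-bs (-0.0266), and otherwise on leaving out 1 library, with ranges of -0.0719 to 0.0449 for mt-Nd1, -0.0531 to 0.0150 for mt-Co1, -0.0209 to 0.0244 for mt-Atp8_6, -0.295 to 0.0422 for mt-Nd6, -0.0661 to 0.155 for Hbb-bs, -0.0848 to 0.371 for Lipe, -0.0223 to 0.242 for Cidea, -0.0577 to 0.251 for Mybpc2 and -0.115 to 0.261 for Wt1, with fewer samples. Of the 27 lists not called, 10 were called under an alternative, 9 of them on leaving out 1 library, and 18 of 29 lists changed direction, 14 of them on leaving out 1 library. Fatty acid oxidation was the 1 list called in both directions. Camera adjusted p-values where the direction turned were, under equal totals, 0.956 for heavy-strand mRNAs, the light-strand list and mitochondrial ribosomal proteins, 0.391 for complex I, 0.860 for glycolysis, 0.993 for cardiac stress, 0.952 for clock genes and 0.996 for fibroblasts. They were 0.995 and 0.997 without a filter for the integrated stress response and clock genes, 0.780 with a mean of at least 50 for the former, and 0.948 in fry for cardiac stress. For lists that turned on leaving out 1 library the adjusted p ran from 1.68e-05 to 0.301 for fatty acid oxidation, 0.0042 to 0.879 for complex II to V, 0.0421 to 0.840 for complex I, 0.0334 to 0.679 for cardiac stress, 0.0267 to 0.703 for extracellular matrix, 0.0164 to 0.880 for erythroid markers, 0.0538 to 0.993 for heavy-strand tRNAs, 0.244 to 0.908 for the light-strand list, 0.519 to 0.966 for the integrated stress response, 0.0803 to 0.933 for p53 targets, 0.305 to 0.840 for clock genes, 0.427 to 0.993 for endothelial, 0.530 to 0.928 for smooth muscle and 0.552 to 0.966 for atrial markers. At these depths, of at least 41979163 reads, the test recovered 12% of simulated 1.2-fold and 76% of 1.5-fold changes in genes with a mean of at least 50, so changes of 1.2-fold were mostly below detection. With only 4 real calls the cutoff was stricter than in the simulation, so real recovery of 1.5-fold changes was likely lower too.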

Other observations

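The tests of cardiomyocyte RNA, a structure of the libraries, mitochondrial RNA of every kind, leukocytes and further antigen presentation genes, and the fit with the fatty acid oxidation covariate, were chosen only after the result was seen, as was the naming of Pdk4, Ucp3, Angptl4, Plin5 and Nppb.

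Several genes picked after their values were seen varied between libraries of the same group. As a set they form no tested list, but Pdk4 and Ucp3 belong to the fatty acid oxidation list and Nppb to the cardiac stress list. Pdk4, a kinase that inhibits pyruvate dehydrogenase, held 5611, 1989 and 1338 normalised counts in control 490, 498 and 502, and 3364, 2038 and 4623 in knockout 492, 499 and 501. Ucp3, a mitochondrial carrier, held 789, 427 and 277 in the controls and 667, 271 and 869 in the knockout-labelled libraries, in the same order. Angptl4, a lipase inhibitor, held 133, 66.8 and 24.4 against 114, 51.1 and 112, and Plin5, a lipid droplet protein, 1301, 915 and 746 against 1140, 717 and 1153. Nppb, a natriuretic peptide, held 953, 1937 and 2237 against 1445, 2297 and 1503. The fatty acid oxidation score was 0.25, -0.062 and -0.20 in the controls and 0.092, -0.18 and 0.096 in the knockout-labelled libraries. The score, Pdk4, Ucp3, Angptl4 and Plin5 were thus higher, and Nppb lower, in control 490, knockout 492 and knockout 501 than in the other 3 libraries. Pdk4 and Ucp3 are part of the score, and all these genes were picked after their values were seen, so they are no separate evidence. With that score as a covariate, limma called 22 features, 18 lower and 4 higher, including all 4 called without it and 20 of the 33 in the authors' deposited table.

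Nuclear transcripts led by Ghitm, Cpe and Pdha1 were lower in the knockout-labelled libraries. The sarcomere and calcium handling list differed by -0.0241 (95% interval -0.101 to 0.0526), where the authors' lower calls had a median of -0.299. This argues against a smaller share of cardiomyocyte RNA large enough to give that median. Those calls were picked for being lower, so a smaller loss stays open. With the fatty acid oxidation score as a covariate all 4 limma calls were kept, with Ghitm at -0.67, Cpe at -0.52 and Pdha1 at -0.33. The score differed between the groups by only 0.0053 (SD 0.232 in control, 0.158 in knockout-labelled libraries), so the covariate could hardly move a group difference. The fit thus cannot decide whether a structure that the score follows lowered these transcripts. C57BL/6J ancestry that differs between the groups stays open. Nnt, which carries a deletion in that strain, varied 1.36-fold between libraries, under the 1.5-fold bound set beforehand for the deletion. Yet Nnt was 410 ± 10.2 in control and 358 ± 43.1 in knockout-labelled libraries (SD, n = 3) without overlap, though not called by limma. How far Nnt falls in a heterozygous library is not known from these data, so the bound cannot settle the question. The 6 libraries make 10 splits, too few for a share under 0.05; 2 of 10 gave as many limma calls (real 4, highest other 26) and 2 of 10 as many DESeq2 calls (real 33, highest other 67). The split with 26 and 67 calls set control 490, knockout 492 and knockout 501, the libraries of higher fatty acid oxidation score, against the rest, with several times the real limma count and more than the real DESeq2 count, which points to a structure of the samples that does not follow the genotype labels, and genotype as the cause of the lower transcripts stays a hypothesis. Only the knockout-labelled libraries carry the Ckmm allele, so its own effect cannot be told apart from loss of Rexo2.

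The 16S rRNA mt-Rnr2 took a larger share of reads in the knockout-labelled libraries. More mitochondrial RNA of every kind is argued against by mt-Rnr2 minus the heavy-strand mRNAs, which was higher by 0.129 on the log2 scale (95% interval 0.0233 to 0.234) with no overlap. Its exact permutation p was 0.1, the smallest possible, and 0.3 when adjusted over the mtDNA measures. Against mt-Rnr1 the groups overlapped, with mt-Rnr2 higher by 0.0842 (exact permutation p = 0.2), so the argument covers the mRNAs only. Weaker removal of ribosomal RNA may still account for it and cannot be told apart from genotype, because Gm42418 and Gm26917, which overlap ribosomal RNA sequence, differed by -0.823 with a 95% interval from -4.21 to 2.56. That width came mainly from Gm42418, with 146900 counts in control 490, 23720 in knockout 501 and between 1398 and 4190 in the other 4 libraries, whereas Gm26917 alone, at 44140 ± 2510 in control and 39530 ± 6450 in knockout-labelled libraries (SD, n = 3), had a log2 fold change of -0.17 with an SE of 0.091, which lies below the 0.15 of mt-Rnr2 and goes against weaker removal. Nuclear rRNA features are no direct measure of how well mitochondrial rRNA was removed, so an effect of genotype on mt-Rnr2 stays a hypothesis.

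The fixed list of interferon-stimulated genes lay higher on average in the knockout-labelled libraries. More leukocytes cannot be told apart from a change within heart cells, because the macrophage markers differed by 0.0384 with a 95% interval from -0.124 to 0.201, which includes the interferon-stimulated median of 0.156. A set of 8 further antigen presentation genes was left after B2m and H2-Q7 were set aside because their values had been seen. It held H2-D1, H2-Q4, H2-T23, H2-M3, Tap2, Tapbp, Psmb10 and Erap1. Of these, 7 had a log2 fold change above 0 and 0 were called by limma. The 2 at an unadjusted p under 0.05 were H2-D1 (0.203) and H2-Q4 (0.296). Both are MHC class I genes like H2-K1 and H2-Q6, and may share reads with them. Tap2, Tapbp, Psmb10 and Erap1 lay at 0.104, 0.0353, 0.0965 and -0.0617. The mean log2 value of the 8 genes was higher by 0.146 (95% interval -0.0229 to 0.315). It was 8.70 in the lowest knockout-labelled library against 8.68 in the highest control. A wider shift of antigen presentation stays open, and the H2 genes may be no separate evidence for it. The real split brought 2 lists past the threshold. As many or more were reached in 9 of 10 splits (highest other 10), which are too few for a share under 0.05. At the preset correlation the interferon list had a camera adjusted p of 7.44e-09 in the real split. Splits that mix the genotypes gave it 7.98e-18, 9.84e-06, 0.000212, 0.000434, 0.012, 0.0515, 0.418, 0.945 and 0.991. Because the list also passed in several of these, its call at that correlation gives genotype no support. A response to genotype stays a hypothesis. The adjusted p of the list was 0.83 at an estimated correlation, a setting with little power here.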
